A study of Mus musculus with 24 samples.

How the data were processed

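Gastrocnemius muscle was taken from C57BL6 mice of both sexes in a design crossing sex with tumour. Mice were injected under the skin at 7 weeks of age with LLC1 cells, a mouse Lewis lung carcinoma line, or with phosphate-buffered saline as vehicle, and the tumour cells were given 3 weeks to grow, per the labels. The 4 groups held 6 mice each, and the titles give every library a mouse number of its own within its group. Each of the 24 libraries was treated as a separate mouse on that basis, and p-values measure the spread between these libraries. Every library of a group carries the same lane in its description and each group has a lane of its own, so lane and group cannot be told apart and lane could not enter any model.

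Poly(A) RNA was made into libraries with version 2 of the TruSeq RNA kit and 12 cycles of PCR, per the labels. That kit keeps no record of the strand. CASAVA, STAR, featureCounts and the build mm10 are named in the submitters' processing notes. Their versions, their options, the annotation release and the treatment of reads over more than 1 gene are not given in the sources used here. The deposited table holds whole-number read counts for 43346 genes in 24 libraries, not normalized. The genes Ube2c and Tnnc2, which overlap on opposite strands, had summed counts in a ratio of 1.0, as arises where a read over both is counted for both. A gene was therefore marked as sharing reads where at least 10% of its exon length in GENCODE M21 overlapped a gene with at least 0.5 times as many counts. That marked 3430 genes, of which 2260 were tested. Without strand, reads of a gene and its antisense partner cannot be told apart. The 37 mitochondrial-encoded genes summed to 0 counts over all libraries, so the 13 mitochondrial subunits of oxidative phosphorylation were not measured. Of the gene identifiers, 42462 were found in GENCODE M21, and 33497 had the same coordinates there. Coordinates are those of the deposited count table (mm10).

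Total counts were 26.2 to 47.4 M (mega-counts) per library, with 23078 to 24556 genes holding at least 1 count. Pairs of libraries within a group were compared by a chi-square statistic over genes with at least 50 counts in the pair. It was 10.05 to 211 per degree of freedom over the 60 pairs, so no library repeated another within sampling noise.

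Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited. The filterByExpr filter left 17773 genes. The fit used TMM normalization factors (0.924 to 1.10), robust dispersion estimates, 4 group means and all 24 libraries, which left 20 residual degrees of freedom. The common biological coefficient of variation was 0.174. Adjusted p-values are Benjamini-Hochberg values over the 17773 genes within a comparison, and a gene was called at an adjusted p under 0.05. Calls given as made with edgeR are those of this fit unless another setting is named. Genes that did not pass here may pass in other edgeR settings. Log2 fold changes are given with the standard error (SE) that follows from the F statistic. The comparisons made were LLC1 against vehicle in females, in males and averaged over the sexes, the interaction of LLC1 with sex, and the sex difference in vehicle and in LLC1 mice. Normalised levels are in CPM, counts per mega-count of the TMM-scaled library size. The median log2 fold change over all genes tested lay between -0.02 and 0.01 in every comparison.

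A set of 38 lists was fixed before the data were examined, 26 of gene groups and 12 of cell type markers. The gene groups were ubiquitin ligases and atrogenes, proteasome subunits, autophagy and lysosome, glucocorticoid-responsive genes, IL-6/STAT3 and acute phase, interferon-stimulated genes, nuclear-encoded and mitochondrial-encoded oxidative phosphorylation, mitochondrial biogenesis and dynamics, the tricarboxylic acid cycle, fatty acid oxidation, glycolysis and glycogen, slow-fibre and fast-fibre sarcomere, denervation and neuromuscular junction, myogenic regulation and growth factors, extracellular matrix, the unfolded protein response, heat shock, cytosolic ribosomal proteins, translation factors and mTORC1 signalling, cholesterol and lipid synthesis, the circadian clock, immediate early genes, androgen-responsive genes in muscle, and the cell cycle. The cell type lists were macrophage and monocyte, neutrophil, T cell and NK cell, B cell and plasma cell, adipocyte, endothelial cell, fibro-adipogenic progenitor, erythroid cell, smooth muscle cell and pericyte, Schwann cell, tendon cell and epithelial (carcinoma) cell. Lists overlap: Cdkn1a, Mt1 and Mt2, for example, stand among both the atrogenes and the glucocorticoid-responsive genes. Cebpb, Cebpd and Lcn2 stand among both the glucocorticoid-responsive and the IL-6/STAT3 and acute phase genes. Muscle itself expresses many marker genes of the other lists. A list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 where at least 3 members were tested, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was also run with the correlation estimated from the data. Fry tested whether the members of a list moved, on balance, one way. Numbers of members in the text are of those tested after the expression filter. These were 11 of 13 listed neutrophil markers, 19 of 27 IL-6/STAT3 and acute phase genes, 4 of 11 T and NK cell markers and 3 of 9 epithelial markers. A gene near 0 in vehicle mice can pass that filter through the LLC1 groups alone.

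The genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls in each sex among called genes with a mean log2 CPM of at least 1 and a symbol that is not a predicted gene model, 5 each way for the sex differences, 18 fixed genes, and up to 4 members of each list by smallest p. Some genes that the rule takes are not reported here. The genes Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y served as a check of the sex labels and are given as raw counts.

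Depth and composition were compared by exact two-sided permutation tests over all assignments of 6 against 6 libraries, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The tests were checked on simulated counts drawn with the real means, depths and dispersions over 17773 genes, of which 200 were changed by a known fold. At 2-fold, 81.3% of changed genes were recovered in the female comparison, 83.9% in the male, 62.9% in the interaction and 80.6% in the sex difference of vehicle mice. At 1.5-fold, 41.1%, 55.9%, 14.7% and 52.9% were recovered in the same order. False calls made up 7.9%, 4.8%, 4.2% and 5.0% of calls.

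Alternatives tried were RLE and upper-quartile normalization, TMM without the 50 most abundant genes, no filter and a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, a fit of only the libraries compared, the title numbers as blocks, an adjusted p of 0.01, a test against a fold change of 1.5, and leaving out each library in turn. Removal of genes that share reads was added after the data were seen. No fold is given for a gene with no count in a group, except as a bound from 3 counts over that group.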

Results

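Gastrocnemius, the large calf muscle, was profiled by poly(A) RNA sequencing in C57BL6 mice carrying LLC1 tumours and in vehicle mice of both sexes. LLC1 is a mouse Lewis lung carcinoma line that grows under the skin and is widely used to model cancer cachexia, the muscle wasting seen with tumours. The series also assessed muscle mass, strength, body weight, mitochondrial function and the fractional rate of protein synthesis, none of which is analysed here. Each of the 4 groups held 6 mice. Total counts averaged 37.6 ± 3.29 M (mega-counts, SD, n = 6) in female LLC1 mice, 37.2 ± 6.48 M in female vehicle mice, 35.9 ± 5.55 M in male LLC1 mice and 35.0 ± 6.16 M in male vehicle mice. Depth did not differ detectably with LLC1 (exact two-sided permutation p = 0.913 in females and 0.840 in males).

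Genes of the sex chromosomes matched the labels in all 24 libraries. Raw counts of Xist, the X-inactivation transcript, were 8217 to 15453 in female and 0 to 8 in male libraries. Those of the Y-linked gene Ddx3y were 2409 to 9038 in males and 0 to 2 in females. Myh4, the myosin heavy chain of the fastest fibres, held 6.59% of all counts. The 10 most abundant genes held 25.2% of counts in male LLC1 mice and 27.4% in male vehicle mice (exact permutation p = 0.0433, 0.216 after adjustment over 10 tests of depth and composition), and 24.9% and 25.5% in females (p = 0.561).

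The effect of LLC1 on muscle was examined in females. Fbxo32 (ENSMUSG00000022358, chromosome 15, 58175879 to 58214892), which encodes the ubiquitin ligase atrogin-1, rose from 244 ± 65.3 to 796 ± 338 CPM (SD, n = 6 per group). Its log2 fold change was 1.71 ± 0.33 (SE, adjusted p = 0.00187), and all 6 LLC1 mice (465 to 1373 CPM) lay above all 6 vehicle mice (139 to 311 CPM). Trim63 (ENSMUSG00000028834, chromosome 4, 134315120 to 134329629), which encodes the ubiquitin ligase MuRF1, rose by 1.22 ± 0.35 (adjusted p = 0.0285), from 167 to 267 CPM in vehicle to 274 to 774 CPM in LLC1 mice. Mt1 and Mt2, which encode metal-binding metallothioneins, rose by 1.85 ± 0.46 and 2.39 ± 0.60 (adjusted p = 0.0148 and 0.0147), and Eif4ebp1, a repressor of cap-dependent translation, by 1.12 ± 0.27 (adjusted p = 0.0121). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722), the cell cycle inhibitor p21, was at 36.5 ± 4.63 CPM with LLC1 and 37.8 ± 8.01 CPM without (log2 fold change -0.05 ± 0.27, adjusted p = 0.932). The call of Trim63 was lost without female LLC1 mouse 2-3 (adjusted p = 0.0824) or female vehicle mouse 2-1 (0.0637) or 2-3 (0.0514), and with no expression filter (0.0602). That of Mt2 was lost with limma-voom (adjusted p = 0.0531).

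Of the 25 ubiquitin ligases and other atrogenes, the genes most often raised in wasting muscle, 7 rose, 0 fell and 18 did not pass in females, and 11 rose and 1 fell when adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 2.39e-04). Of 24 glucocorticoid-responsive genes, 6 rose and 18 did not pass (11 higher and 1 lower adjusted over the list alone, median 0.54, camera adjusted p = 8.47e-06), led by Lcn2 and the transcription factor gene Cebpd, which rose by 1.61 ± 0.40 (adjusted p = 0.0143). Both Lcn2 and Cebpd also stand in the IL-6/STAT3 and acute phase list, and Mt1 and Mt2 among the atrogenes. Of 27 genes of autophagy and the lysosome, 7 rose and 20 did not pass (8 higher adjusted over the list alone, median 0.15, camera adjusted p = 2.31e-04). Among them were Map1lc3b (0.51 ± 0.13), Map1lc3a (0.31 ± 0.07) and Uvrag (0.43 ± 0.10). Of 31 proteasome subunits, 2 rose, Psmd8 (0.65 ± 0.17) and Psmd2 (0.49 ± 0.15), also adjusted over the list alone, while the median was 0.15 (camera adjusted p = 0.00159). Psmd2 was not called without any of female LLC1 mice 1-5, 2-3 and 2-4 and female vehicle mice 1-1, 1-3 and 2-1 (adjusted p = 0.0595, 0.0643, 0.0566, 0.0503, 0.0513 and 0.0525). None of these 4 lists was called with the correlation between genes estimated from the data: adjusted p = 0.435, 0.409, 0.471 and 0.912 with an estimated correlation.

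Inflammatory and blood cell transcripts made up the largest rises in females. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), a subunit of the neutrophil protein calprotectin, rose from 0.490 ± 0.128 to 38.9 ± 15.5 CPM (log2 fold change 6.30 ± 0.33, n = 6 per group, adjusted p = 1.92e-11), with every LLC1 mouse at 23.4 CPM or more. Its partner S100a8 rose 84.4-fold (SE 0.40 in log2), the neutrophil collagenase Mmp8 by 6.59 ± 0.54, the chemokine receptor Cxcr2 by 5.13 ± 0.33 and Retnlg by 4.35 ± 0.45 (5.21 without female vehicle mouse 1-3). All 11 neutrophil markers tested, of 13 listed, rose, over all genes and adjusted over the list alone (median 6.19, camera adjusted p = 4.64e-61, adjusted p = 8.94e-05 with an estimated correlation). Markers near 0 in vehicle mice can enter the test through the LLC1 groups alone. All 7 erythroid markers rose too (also adjusted over the list alone, median 3.00, camera adjusted p = 3.64e-09, adjusted p = 0.273 with an estimated correlation), with the red cell membrane gene Slc4a1 at 5.32 ± 0.82. Without female LLC1 mouse 2-4 the median was 1.82, Slc4a1 stood at 3.83, and the rise of Apol11b was 3.58 in place of 5.62. Of 14 macrophage and monocyte markers 0 passed with edgeR, adjusted over the list alone too, with a median of 0.12 (camera adjusted p = 0.322, and 0.0131 without female LLC1 mouse 2-4). The list was also called with the full title number as a block, as given with the processing below.

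Of 19 genes of IL-6/STAT3 signalling and the acute phase, 10 rose and 9 did not pass in females (13 higher and 1 lower adjusted over the list alone, median 0.75, camera adjusted p = 9.11e-14, adjusted p = 0.0998 with an estimated correlation). The oncostatin M receptor gene Osmr rose by 1.51 ± 0.13 (adjusted p = 1.95e-08), the feedback inhibitor Socs3 by 1.55 ± 0.24 (1.83e-04), the lipocalin Lcn2 by 2.74 ± 0.35 (1.84e-05) and the NF-kappaB cofactor Bcl3 by 1.48 ± 0.22 (1.01e-04). All 6 LLC1 mice had more Socs3 (6.08 to 21.3 CPM) than any vehicle mouse (3.11 to 6.03 CPM). Il6ra, the IL-6 receptor gene, rose by 1.25 ± 0.38 (adjusted p = 0.0404), a call lost without any of 8 libraries: female LLC1 mice 1-5, 2-3, 2-4 and 2-5 (adjusted p = 0.0572, 0.0997, 0.0503 and 0.0572) and female vehicle mice 1-3, 2-1, 2-2 and 2-3 (0.0623, 0.0778, 0.0757 and 0.0814). It was also lost with limma-voom (0.0648) and with no filter (0.0787). Serpina3n, an acute phase protease inhibitor, was at 1.22 ± 0.42 (adjusted p = 0.0688) and passed with DESeq2 (0.0403), with limma-voom with sample weights (1.53, 0.00984) and without female LLC1 mouse 2-4 (0.0302) or 2-5 (0.0398) or female vehicle mouse 1-3 (0.0336). The neutrophil and erythroid markers rose in the same group of mice.

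Transcripts of mitochondrial energy metabolism were lower in female LLC1 mice. Of 77 nuclear-encoded subunits of oxidative phosphorylation, 47 fell and 30 did not pass, and 69 fell when adjusted over the list alone (median log2 fold change -0.35, camera adjusted p = 7.49e-26). Examples were Ndufs1 of complex I (-0.48 ± 0.10, adjusted p = 0.00408) and Atp5g3 of the ATP synthase (-0.48 ± 0.11, 0.00510). The 13 subunits encoded in the mitochondrial genome had 0 counts in every library and were not tested. Of 21 genes of the tricarboxylic acid cycle, 11 fell and 10 did not pass (14 lower adjusted over the list alone, median -0.28, camera adjusted p = 4.98e-07), among them Dlst (-0.31 ± 0.07), Idh3a (-0.48 ± 0.11) and Dlat (-0.43 ± 0.10). Both lists stood at an adjusted p = 0.409 with an estimated correlation. Ppargc1a, the coactivator PGC-1alpha, was at -0.17 ± 0.12 (adjusted p = 0.380), and at -0.32 (0.0346) without female LLC1 mouse 2-1.

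Several extracellular matrix genes were lower in female LLC1 mice. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), a fibrillar collagen gene, fell from 560 ± 219 to 168 ± 60.6 CPM (log2 fold change -1.74 ± 0.40, n = 6 per group, adjusted p = 0.00805), and no LLC1 mouse (84.2 to 240 CPM) reached a vehicle mouse (299 to 867 CPM). Of 28 matrix genes, 11 fell, 1 rose and 16 did not pass (13 lower and 2 higher adjusted over the list alone, median -0.47, camera adjusted p = 7.25e-05, adjusted p = 0.692 with an estimated correlation). The mean of the matrix genes per mouse differed by -0.52 log2 units (exact permutation p = 0.136, 0.200 after adjustment over 22 tests of such scores, n = 6 per group). Col5a1 was at -1.32 ± 0.27, Col6a2 at -1.34 ± 0.29 and Lum at -0.88 ± 0.21. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), the main collagen of tendon and fascia, was at -1.58 ± 0.46 (adjusted p = 0.0337). That call was lost with no filter (adjusted p = 0.0682) and without any of female LLC1 mice 1-4, 2-3, 2-4 and 2-5 (0.0620, 0.0858, 0.0673 and 0.0567) or female vehicle mice 1-1, 1-3 and 2-1 (0.0720, 0.0872 and 0.0564). It also ended with either form of the title numbers as a block, as given with the processing below. Among 10 markers of fibro-adipogenic progenitors, the matrix-producing mesenchymal cells of muscle, 2 fell and 1 rose (6 and 2 adjusted over the list alone, median -0.38, camera adjusted p = 0.0398, adjusted p = 0.770 with an estimated correlation). That list was not called without female LLC1 mouse 2-4 (0.269) or 2-5 (0.225) or female vehicle mouse 1-1 (0.112), 1-3 (0.0925) or 1-4 (0.0754). Of 9 tendon cell markers 0 passed with edgeR, adjusted over the list alone too (median -0.21, camera adjusted p = 0.313, and 0.0171 without female LLC1 mouse 2-1 or 0.0335 without female vehicle mouse 2-3).

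The other large falls in females were in Actc1, the cardiac isoform of alpha-actin (-2.25 ± 0.39, adjusted p = 8.08e-04), the forkhead gene Foxo6 (-1.77 ± 0.27) with its opposite-strand neighbour Foxo6os (-2.11 ± 0.33), Nrep (-1.78 ± 0.34), the collagen gene Col5a3 (-1.63 ± 0.19), Ostn, which encodes the secreted peptide musclin (-1.60 ± 0.29), and the phosphatase gene Dupd1 (-1.76 ± 0.40, and -2.39 without female LLC1 mouse 2-5). In all, edgeR called 884 genes higher and 879 lower with LLC1 in females, 1763 of 17773 tested, and 4534 at an unadjusted p under 0.05. Of the 1763, 235 were at least 2-fold higher, 141 at least 2-fold lower, and 147 share reads with an overlapping gene. Without female LLC1 mouse 2-3 or female vehicle mouse 2-1 the count was 919 or 1100.

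The effect of LLC1 was then examined in males. Fbxo32 rose from 393 ± 84.8 to 2328 ± 1256 CPM (SD, n = 6 per group, log2 fold change 2.57 ± 0.34, adjusted p = 1.66e-05), with all 6 LLC1 mice (909 to 3974 CPM) above all 6 vehicle mice (291 to 517 CPM). Trim63 rose by 2.89 ± 0.37 (adjusted p = 1.32e-05, 457 to 2758 against 163 to 281 CPM) and Cdkn1a by 2.23 ± 0.28 (1.14e-05, 36.7 to 128 CPM, above all 6 vehicle mice, whose mean was 16.8 ± 6.60 CPM). Foxo1, a transcription factor upstream of both ligases, rose by 1.52 ± 0.40 (0.00538), and Mstn, the muscle growth inhibitor myostatin, by 0.70 ± 0.18 (0.00485). Igf1, a growth factor for muscle, fell by 0.87 ± 0.23 (0.00616). Mt1 and Mt2 rose by 2.48 ± 0.48 and 2.65 ± 0.61 (6.01e-04 and 0.00237), and Eif4ebp1 by 2.08 ± 0.28 (2.17e-05). The corresponding female values were 0.80 ± 0.39 for Foxo1, 0.10 ± 0.18 for Mstn and -0.37 ± 0.23 for Igf1, none of which passed (adjusted p = 0.203, 0.777 and 0.326).

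Of the 25 atrogenes, 16 rose, 1 fell and 8 did not pass in males (16 and 2 adjusted over the list alone, median 0.72, camera adjusted p = 3.19e-07). All 31 proteasome subunits rose, also adjusted over the list alone (median 0.70, camera adjusted p = 1.85e-13), with Psmc2 at 0.84 ± 0.14, Psmd8 at 1.00 ± 0.17 and Psmd7 at 0.58 ± 0.10. Of 27 autophagy and lysosome genes, 18 rose and 1 fell, adjusted over the list alone too (median 0.29, camera adjusted p = 4.73e-06), among them Map1lc3b (0.84 ± 0.13), the mitophagy receptor Bnip3 (1.27 ± 0.20) and the initiating kinase Ulk1 (0.71 ± 0.13). Of 24 glucocorticoid-responsive genes 18 rose and 6 did not pass, adjusted over the list alone too (median 0.85, camera adjusted p = 8.60e-09), including Sesn1 (2.23 ± 0.33) and Cebpd (2.52 ± 0.42). These 4 lists were not called when the correlation was estimated: adjusted p = 0.459, 0.562, 0.554 and 0.459 with an estimated correlation.

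Transcripts of the translation apparatus rose in males. Of 78 cytosolic ribosomal proteins, 71 rose and 7 did not pass (73 adjusted over the list alone, median 0.34, camera adjusted p = 5.24e-17, adjusted p = 0.562 with an estimated correlation). Examples were Rps27 (0.65 ± 0.10) and Rps20 (0.50 ± 0.09). In females 0 of the 78 passed with edgeR, adjusted over the list alone too, with a median of 0.03 (camera adjusted p = 0.200), while Rps27 passed in a fit of female mice alone (0.27, adjusted p = 0.0441), with limma-voom with sample weights (0.0454) and without male LLC1 mouse 1-5 (0.0377). Leaving out female LLC1 mouse 1-5 or 2-3 or female vehicle mouse 2-1, 2-2 or 2-3 gave that list camera adjusted p = 0.0315, 0.0387, 0.00962, 0.00239 and 0.0265, with medians of 0.07, 0.07, 0.08, 0.10 and 0.08. Of 26 translation factors and genes of mTORC1 signalling, 14 rose and 2 fell in males (17 and 3 adjusted over the list alone, median 0.27, camera adjusted p = 4.62e-04, adjusted p = 0.554 with an estimated correlation), and 6 rose in females (9 and 1, median 0.24, camera adjusted p = 1.33e-04, adjusted p = 0.409 with an estimated correlation). The movers included factors that drive translation, such as Eif4a1 in males (0.75 ± 0.14) and Eef2 in females (0.43 ± 0.08), and repressors, such as Eif4ebp1 in both sexes and Sesn1 in males.

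The neutrophil and erythroid rise was also present in males. S100a9 rose by 6.30 ± 0.32 (0.344 to 0.902 CPM in vehicle and 24.4 to 69.5 CPM in LLC1 mice, adjusted p = 1.47e-11), S100a8 by 6.77 ± 0.41, Mmp8 by 6.70 ± 0.55, Chil3 by 5.85 ± 0.57, Cxcr2 by 5.17 ± 0.33, the cytokine Il1b by 5.04 ± 0.31 and Retnlg by 4.77 ± 0.47. All 11 neutrophil markers tested, of 13 listed, rose, adjusted over the list alone too (median 5.70, 6.42 without male vehicle mouse 1-1, camera adjusted p = 2.19e-33, adjusted p = 0.00395 with an estimated correlation). Of these, Ltf had 435 counts over the LLC1 group and 0 over the vehicle group, at least 141-fold higher against a floor of 3 counts over the group, and the median was 5.70 with Ltf at that bound. All 7 erythroid markers rose, adjusted over the list alone too (median 1.81, camera adjusted p = 3.49e-04, adjusted p = 0.562 with an estimated correlation), with Slc4a1 at 4.69 ± 0.85. Of the 19 IL-6/STAT3 and acute phase genes 15 rose, adjusted over the list alone too (median 0.81, camera adjusted p = 1.64e-09, adjusted p = 0.354 with an estimated correlation). Osmr rose by 1.43 ± 0.13, Socs3 by 1.37 ± 0.24, Bcl3 by 1.87 ± 0.23, Il6ra by 2.53 ± 0.39 and Serpina3n by 1.90 ± 0.44. Of 14 macrophage markers 1 rose, Cd14 (0.68 ± 0.19), adjusted over the list alone too (median 0.09, camera adjusted p = 0.427). The list was called with either form of the title numbers as a block, as given with the processing below. The chemokine receptor gene Ccr2 was at 0.53 (adjusted p = 0.0541) and passed with DESeq2 (0.0361), limma-voom with sample weights (0.0292) and a fit of male mice alone (0.0207), in which Ctss passed too (0.0452).

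Of the 77 nuclear-encoded oxidative phosphorylation subunits 30 fell in males, adjusted over the list alone too (median -0.22, camera adjusted p = 3.19e-07, adjusted p = 0.597 with an estimated correlation), with Atp5a1 at -0.44 ± 0.08 and Ndufs1 at -0.52 ± 0.10. Of 21 tricarboxylic acid cycle genes 12 fell (14 adjusted over the list alone, median -0.25, camera adjusted p = 1.46e-05, adjusted p = 0.562 with an estimated correlation), with Dlat at -0.68 ± 0.10 and Idh3a at -0.56 ± 0.11. Ppargc1a fell by 0.35 ± 0.12 (adjusted p = 0.0238), a call lost without male LLC1 mouse 1-5 (0.0598) or 2-5 (0.0525) or male vehicle mouse 2-4 (0.0560). Pdk4, a brake on pyruvate oxidation, rose 2.82-fold (adjusted p = 0.0460), from 356 ± 172 to 1004 ± 587 CPM. That call was lost without any of 12 libraries, at an adjusted p of 0.0515 to 0.122, the highest without male LLC1 mouse 2-4. The other 11 were female LLC1 mouse 2-4, female vehicle mice 1-3 and 2-3, male LLC1 mice 1-5, 2-1 and 2-2, and male vehicle mice 1-1, 1-2, 1-3, 1-4 and 2-4. It was also lost with upper-quartile scaling (0.0544), no filter (0.0926) and limma-voom (0.0776, or 0.0682 with sample weights). In females Pdk4 was at 1.72 ± 0.58 (adjusted p = 0.0613), and passed with DESeq2 (0.0317), with a 1 CPM filter (0.0494) and without female LLC1 mouse 1-5 (0.0356), female vehicle mouse 2-2 (2.46, 0.00931) or male LLC1 mouse 1-4 (0.0464). Myh4 was at -0.30 ± 0.13 in males (adjusted p = 0.0743) and -0.11 ± 0.13 in females (0.646), and Myh7, the slow myosin heavy chain, at 0.06 ± 0.50 and 0.33 ± 0.50 (0.936 and 0.730). In males Myh4 passed without male LLC1 mouse 2-2 (0.0320) or male vehicle mouse 1-3 (0.0232), and with upper-quartile scaling (0.0456).

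Matrix transcripts fell in males as well. Of 28 genes, 17 fell, 1 rose and 10 did not pass (18 and 3 adjusted over the list alone, median -0.93, camera adjusted p = 2.70e-07, adjusted p = 0.562 with an estimated correlation). Col1a1 fell from 376 ± 224 to 78.2 ± 39.7 CPM (log2 fold change -2.27 ± 0.47, n = 6 per group, adjusted p = 0.00113), with no LLC1 mouse (at most 122 CPM) reaching a vehicle mouse (206 to 800 CPM). Col3a1 was at -2.40 ± 0.41, Col6a2 at -1.96 ± 0.29 and Col5a1 at -1.84 ± 0.28. Fibro-adipogenic progenitor markers fell with them, 7 of 10 with 1 rise, adjusted over the list alone too (median -0.51, camera adjusted p = 0.0107, adjusted p = 0.593 with an estimated correlation), as did 5 of 9 tendon cell markers, adjusted over the list alone too (median -1.33, camera adjusted p = 0.0193, adjusted p = 0.597 with an estimated correlation). The tendon markers included tenomodulin (Tnmd, -2.15 ± 0.58) and keratocan (Kera, -2.02 ± 0.56), and the list was not called without male LLC1 mouse 1-4 (0.0524) or male vehicle mouse 1-3 (0.0593).

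The remaining large falls in males were Foxo6os (-2.62 ± 0.36), Foxo6 (-2.19 ± 0.30), Nrep (-2.22 ± 0.34), the potassium channel gene Kcng4 (-2.46 ± 0.36), the matrix gene Cilp2 (-2.19 ± 0.53) and Cyp26b1, which encodes an enzyme of retinoic acid breakdown (-2.34 ± 0.71). Cyp26b1 was not called without male vehicle mouse 1-3 (-1.44, adjusted p = 0.0872) or with limma-voom (0.0636). EdgeR called 3462 genes higher and 2987 lower in males, 6449 in all, and 8135 at an unadjusted p under 0.05. Of the 6449, 547 were at least 2-fold higher, 494 at least 2-fold lower, and 666 share reads.

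**Figure D1:**
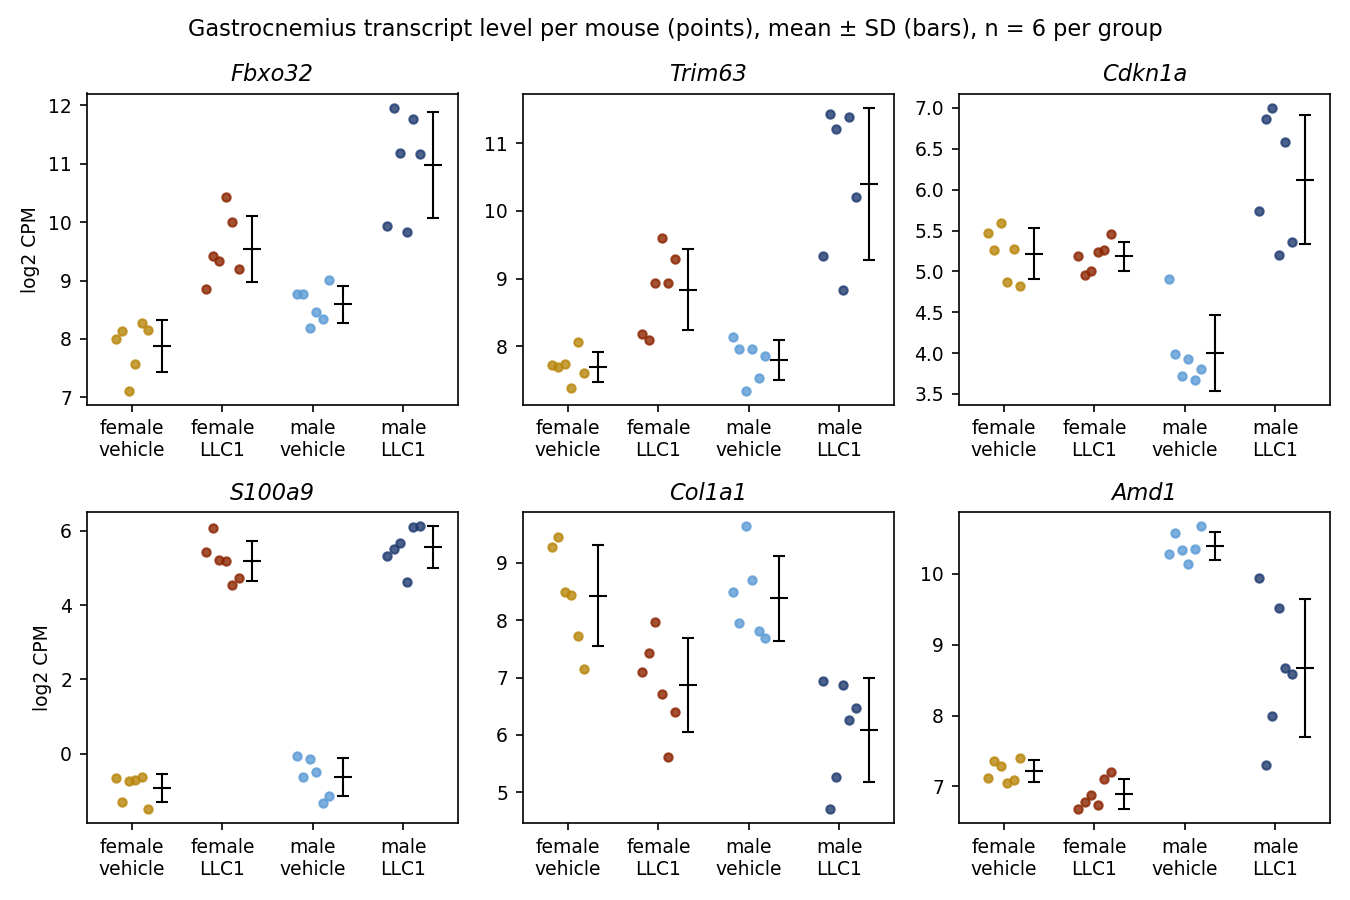
Level of Fbxo32, Trim63, Cdkn1a, S100a9, Col1a1 and Amd1 in log2 CPM (vertical axis) for each of the 4 groups of 6 mice, with a point per mouse and the mean ± SD. Fbxo32 lies at 465 to 1373 CPM in female LLC1 mice and 909 to 3974 CPM in male LLC1 mice, above all vehicle mice of the same sex, whereas Cdkn1a overlaps between female groups and parts in males.

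The effects in the sexes were compared over all 17773 genes. Their log2 fold changes were correlated across genes, which are not independent replicates (Pearson r = 0.788, Spearman rho = 0.662). In settings chosen after the data were seen, r was 0.322 with no filter and 0.419 with DESeq2. The 2 comparisons share no library. Of 6856 genes called in either sex, 6255 (91.2%) had the same sign in both, against 74.4% of all genes. EdgeR called 667 genes higher in both sexes where independent lists would share 172, and 688 lower where they would share 148, and 1 more gene was called in both with opposite signs. A further 5093 genes were called in males without a call in females and 407 in females without a call in males.

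**Figure D2:**
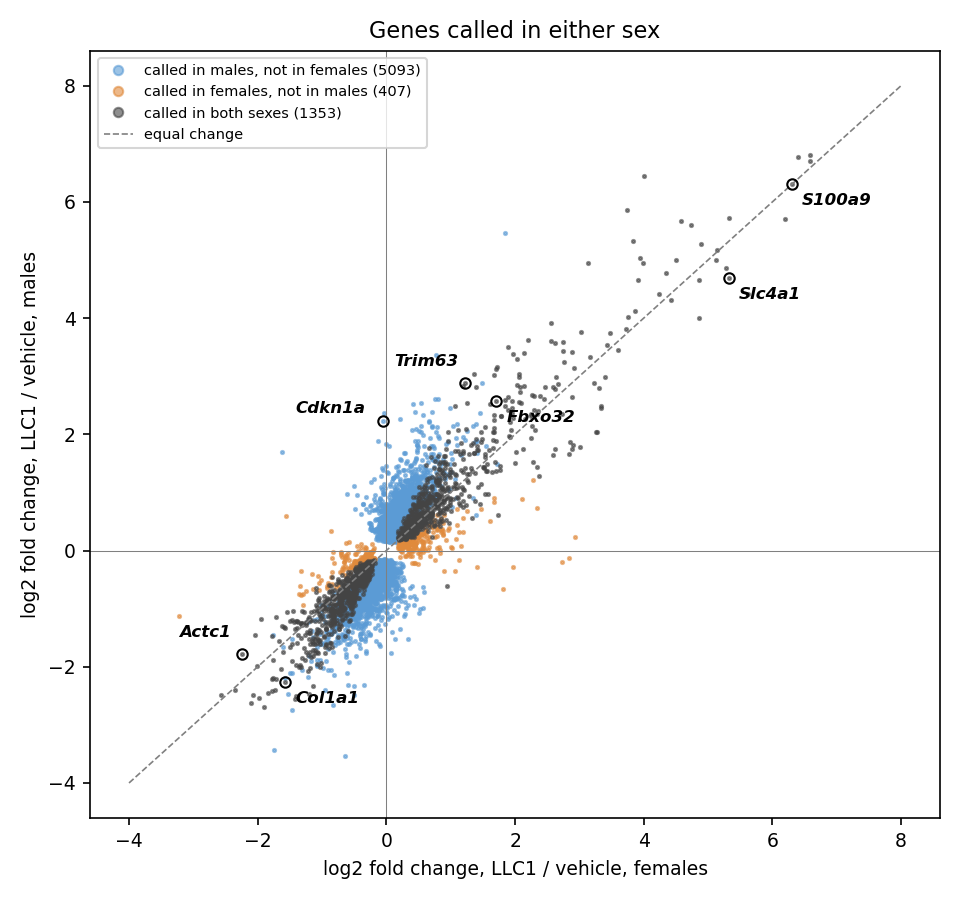
Log2 fold change of LLC1 against vehicle in females (horizontal axis) and males (vertical axis) for each gene called in either sex, coloured by the sex or sexes in which it was called, with a dashed line at equal change and genes with a group at 0 counts not drawn. Of the 1356 genes called in both sexes, 3 of them not drawn, 1355 have the same sign.

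Whether LLC1 acted differently in the sexes was tested as the interaction, written as the female minus the male log2 fold change. Cdkn1a had the smallest adjusted p, with an interaction of -2.28 ± 0.39 (adjusted p = 0.0950): it rose in males by 2.23 and stood at -0.05 in females. The interaction of Trim63 was -1.67 ± 0.49 (0.243) and that of Fbxo32 -0.86 ± 0.45 (0.434), and the clock genes Per2 (1.54 ± 0.31), Hlf (1.15 ± 0.24) and Arntl (-1.43 ± 0.31) stood at an adjusted p of 0.154. With edgeR 0 genes passed, against 2191 at an unadjusted p under 0.05, while DESeq2 called 44 (25 higher and 19 lower), limma-voom 0, and limma-voom with sample weights 2. DESeq2 called Cdkn1a (1.08e-05), Per2 (0.00289), Hlf (0.00730) and Arntl (0.00953). With the first digit of the title numbers as a block edgeR called these genes too, as given with the processing below. Leaving out a library gave 7 genes without male LLC1 mouse 1-4, 6 without 2-2, 1 without 2-5, 1 without male vehicle mouse 1-1 and 2 without 1-3. Cdkn1a passed without male LLC1 mouse 1-4 (0.0292), 2-2 (0.0121) or 2-5 (0.0234) or male vehicle mouse 1-1 (0.00758), and Hlf without male LLC1 mouse 2-2 (0.0387).

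Camera called 13 of 37 lists in the interaction, 6 higher and 7 lower in females relative to males. Proteasome subunits had a median of -0.47 (camera adjusted p = 2.80e-13), glucocorticoid-responsive genes -0.47 (4.42e-04), atrogenes -0.44 (5.14e-04) and cytosolic ribosomal proteins -0.31 (7.51e-27). Adjusted over the list alone, 40 ribosomal proteins, 18 proteasome subunits, 3 atrogenes and 2 glucocorticoid-responsive genes passed, all lower in females relative to males, where 0 did over all genes with edgeR. None of the 13 lists was called with the correlation estimated: adjusted p = 0.812 to 0.936 with an estimated correlation.

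**Figure D3:**
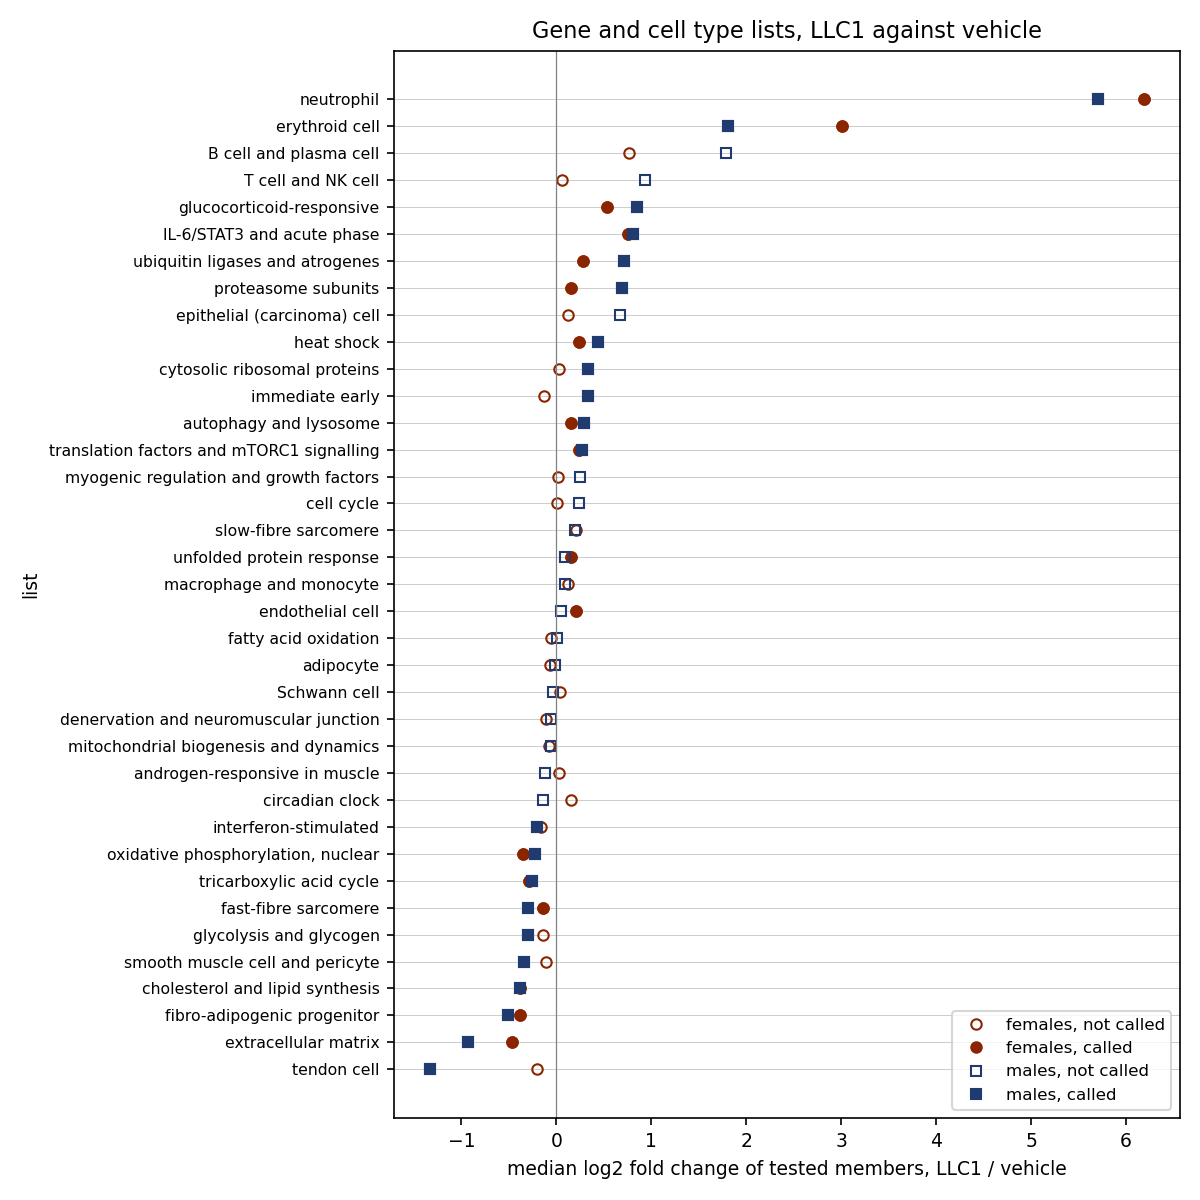
Median log2 fold change of LLC1 against vehicle over the tested members of each gene list, in females and males, with filled points for lists called by camera at its preset correlation. The neutrophil list lies farthest from 0, at 6.19 in females and 5.70 in males, and the proteasome list at 0.15 and 0.70.

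Averaged over the sexes, Fbxo32 rose by 2.14 ± 0.23 (adjusted p = 6.23e-07), Trim63 by 2.06 ± 0.25 (2.84e-06), Cdkn1a by 1.09 ± 0.19 (1.61e-04), Lcn2 by 3.17 ± 0.26 (4.15e-09), Pdk4 by 1.61 ± 0.41 (0.00353) and Mstn by 0.40 ± 0.13 (0.0155), each over 12 LLC1 and 12 vehicle mice. Col1a1 fell by 1.92 ± 0.33 (1.29e-04), Igf1 by 0.62 ± 0.16 (0.00452) and Ppargc1a by 0.26 ± 0.08 (0.0153). Of these genes, Cdkn1a, Pdk4, Mstn, Igf1 and Ppargc1a were called in males and not in females. Their averages therefore do not show a change in each sex, and that of Cdkn1a comes from its rise in males. Myh4 was at -0.20 ± 0.09 (0.0775), and passed without female LLC1 mouse 2-5 (0.0376), male LLC1 mouse 2-2 (0.0391) or male vehicle mouse 1-3 (0.0341), and with upper-quartile scaling (0.0490). The fit called 3772 genes higher and 3598 lower, 7370 in all, with 360 at least 2-fold higher and 270 at least 2-fold lower.

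The sexes were compared in vehicle mice, as the female minus the male log2 level. Amd1 was lower in females by -3.18 ± 0.30 (adjusted p = 1.10e-07), its copy Amd2 by -3.24 ± 0.30 (9.84e-08) and Odc1 by -1.59 ± 0.14 (1.94e-08), with the spermine oxidase gene Smox at -1.57 ± 0.31 (0.00361). Amd1 and Amd2 are near-identical copies, so how reads were split between them is uncertain. These genes stand among the 15 androgen-responsive genes, of which 7 were lower, 0 higher and 8 did not pass, adjusted over the list alone too (median -0.36, camera adjusted p = 1.95e-09, adjusted p = 0.00205 with an estimated correlation). With LLC1, Amd1 and Amd2 fell in males by 1.48 ± 0.28 and 1.56 ± 0.27, and Odc1 rose in females by 0.60 ± 0.14 and in males by 0.93 ± 0.14. The transporter gene Slc15a5 was lower in females (-5.16 ± 0.34, adjusted p = 1.11e-10, 0.138 to 0.404 against 5.56 to 17.0 CPM). The beta-3 adrenergic receptor gene Adrb3 (2.37 ± 0.48, 0.00421) and the lipase gene Pnpla3 (2.08 ± 0.35, 6.27e-04) were higher, as was Adora1 (1.99 ± 0.47, 0.0125), which shares reads with its neighbour Mybph. Cdkn1a was higher in females too (1.18 ± 0.28, 0.0118).

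Of the 78 cytosolic ribosomal proteins, 52 were higher in female vehicle mice (72 adjusted over the list alone, median 0.32, camera adjusted p = 2.99e-28, adjusted p = 0.515 with an estimated correlation), such as Rps2 (0.45 ± 0.07) and Rplp0 (0.47 ± 0.08). Markers of other cell types were higher with them. Of 9 Schwann cell markers 7 were higher (8 adjusted over the list alone, median 0.86, camera adjusted p = 5.07e-06), such as Sox10 (0.95 ± 0.21) and Pmp22 (0.86 ± 0.19), and of 11 adipocyte markers 2 were higher (9 adjusted over the list alone, median 0.95, camera adjusted p = 1.28e-05), Car3 (0.74 ± 0.15) and Retn (1.70 ± 0.36). Both stood at an adjusted p = 0.515 with an estimated correlation. Of 14 slow-fibre genes 0 passed with edgeR, 5 were higher adjusted over the list alone, and the median was 0.85 (camera adjusted p = 0.00119, adjusted p = 0.878 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 1 higher member, Cox8a, 0 adjusted over the list alone, and a median of 0.14 (camera adjusted p = 0.0110, adjusted p = 0.997 with an estimated correlation). That list was not called without female vehicle mouse 2-1 (0.08, 0.175), 2-2 (0.08, 0.141) or 2-3 (0.0928) or male vehicle mouse 2-5 (0.124), and Cox8a itself (0.49 ± 0.14) not without any of 6 vehicle mice, female 1-1, 2-1 and 2-2 and male 1-1, 1-2 and 2-5 (adjusted p = 0.0635 to 0.0818). EdgeR called 524 genes higher and 583 lower in females, 1107 in all, of which 99 share reads. The count was 731 without female vehicle mouse 2-2 and 659 without male vehicle mouse 2-5.

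Among LLC1 mice, females had lower levels of Fbxo32 (-1.55 ± 0.32, adjusted p = 0.00371), Trim63 (-1.78 ± 0.35, 0.00259), Cdkn1a (-1.10 ± 0.27, 0.00921) and Mstn (-0.74 ± 0.18, 0.00882) than males. Il6ra was at -1.37 ± 0.37 (0.0159), a call lost without male LLC1 mouse 1-5 (-1.02, 0.0656), with limma-voom (0.0646) and in a fit of LLC1 mice alone (0.0756). Slc15a5 was lower in females (-4.89 ± 0.34, 2.69e-10), and Mybph, a myosin-binding protein gene, higher (2.63 ± 0.52, 0.00262), as was Adora1 (2.59 ± 0.48, 0.00163). The interferon-stimulated gene Isg15 was at 1.98 ± 0.55 (0.0179), but at 0.64 (0.105) without female LLC1 mouse 2-4, at an adjusted p of 0.0506 without male LLC1 mouse 1-5, and at 0.103 with limma-voom. EdgeR called 1078 genes higher and 1709 lower in females, 2787 in all, of which 290 share reads. A fit of the LLC1 mice alone called 966. The count was 1815 without female LLC1 mouse 1-4, 1606 without male LLC1 mouse 2-4, 1638 without male LLC1 mouse 1-5 and 1749 without male LLC1 mouse 2-1.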

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

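Of the tests in this part, those of residual blood, of haemoglobin copies, of deeper male libraries and without genes that share reads were chosen only after the result was seen. The 22 tests of per-mouse scores were adjusted together, and the adjusted p follows the exact one. Each group has a lane of its own, so differences between lanes and between groups cannot be told apart for any pattern described here.

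Neutrophil and erythroid transcripts were higher in LLC1 muscle of both sexes, with the most abundant, Hbb-bs and Hba-a1, at a mean of 9.65 and 9.26 log2 CPM. More residual blood of unchanged makeup would raise neutrophil, red cell and lymphocyte transcripts alike, if all of them came from blood. The neutrophil score rose beyond the erythroid score by 1.93 log2 units in males (-4.31 against -6.24, n = 6 per group). In females the neutrophil and erythroid scores rose beyond the lymphocyte score by 4.20 and 2.92. Each of these differences had an exact permutation p = 0.00217, the smallest these groups can give (adjusted 0.00476). The lymphocyte score holds Thy1, which fell in both sexes, and muscle itself expresses many marker genes. The comparisons with that score therefore do not by themselves exclude residual blood in females. Reads shared between haemoglobin copies would not raise the erythroid members that are not haemoglobin genes, and all 3 of these were higher in both sexes. The neutrophil minus erythroid score in females did not decide either, at 1.27 (exact permutation p = 0.117, adjusted 0.184). That result depends on female LLC1 mouse 2-4, without which it was 1.96 (exact permutation p = 0.00217). With each other female library left out the exact permutation p was 0.1126 to 0.2165. Residual blood also stays open for red cells in males, where the median B cell marker change was 1.79 (0.58 without male LLC1 mouse 1-4) against an erythroid median of 1.81, although the erythroid score rose beyond the lymphocyte score by 2.09 (exact permutation p = 0.0152, adjusted 0.0256). A changed makeup of the blood, or neutrophils within the muscle, could also account for the rise as a hypothesis tied to the tumour, and neither was tested.

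More genes passed in males (6449) than in females (1763). Deeper male libraries are argued against, since their mean total count differed from the female one by -1.98 M (35.4 against 37.4 M). A smaller spread between male mice was not found: the common biological coefficient of variation was 0.181 in males and 0.167 in females, a ratio of 1.08. These values come from a fit of each sex alone. The counts of called genes come from a fit in which all libraries share the spread of a gene. The comparison of spreads therefore cannot decide why more genes passed in males. A larger response of male LLC1 mice stays open: the slope of each mouse on the averaged LLC1 effect was 1.11 ± 0.398 in males (0.569 to 1.56) and 0.787 ± 0.0873 in females (0.689 to 0.911, SD, n = 6 per group, exact two-sided permutation p = 0.0866). A difference in tumour burden between the sexes could not be examined, since no tumour measure was used here.

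Cytosolic ribosomal protein transcripts were higher in male LLC1 than in male vehicle muscle. A trend with transcript length, GC content and mean expression between libraries is argued against as the whole explanation. The difference of the ribosomal score was 0.34 log2 units before and 0.24 after removing that trend per mouse (n = 6 per group, exact permutation p = 0.00866, adjusted 0.0173). The part removed may follow from the trend. A single male library is argued against, since at least 60 of 78 members passed with each male library left out, the lowest without male LLC1 mouse 1-5. Reads shared with overlapping genes are argued against too, since 69 of the 75 members without such an overlap rose. The list was also lower in male than in female vehicle mice. The ribosomal score averaged 6.92 in male vehicle mice, against 7.26 in male LLC1, 7.24 in female vehicle and 7.27 in female LLC1 mice. It was thus the male vehicle group that stood apart from the other groups. The lane of the male vehicle group stays open, as does an effect of the tumour, which was not tested apart from it.

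Other splits of the same libraries were drawn for each comparison, 100 for each with the real one included. Only the real split gave as many genes for the effect in females (1763 genes, at most 630 in another split, 1 of 100 splits as large), in males (6449, at most 4578, 1 of 100), averaged over the sexes (7370, at most 1867, 1 of 100) and for the sex difference in vehicle mice (1107, at most 76, 1 of 100). Chance is thus unlikely there, though 100 splits cannot exclude it. For the sex difference in LLC1 mice 2 of 100 splits were as large, and 1 of the others gave 2876 genes against the real 2787, so chance is not excluded. For the interaction, 7 of 100 splits gave as many genes at an unadjusted p under 0.05 as the real 2191, up to 2851. That measure was taken because 0 genes passed there with edgeR. These splits exchanged sex labels among vehicle mice and among LLC1 mice. Real differences between the sexes therefore enter them, so they cannot decide about the interaction.

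The effect of LLC1 differed between the sexes for 13 lists by camera at its preset correlation, and for 0 of them with the correlation estimated (adjusted p = 0.812 to 0.936 with an estimated correlation). The medians, female minus male, were -0.44 for atrogenes, -0.47 for proteasome subunits, -0.15 for autophagy and lysosome, -0.47 for glucocorticoid-responsive genes, 0.26 for interferon-stimulated genes, -0.13 for nuclear-encoded oxidative phosphorylation, 0.49 for extracellular matrix, -0.31 for cytosolic ribosomal proteins, 0.29 for the circadian clock, -0.41 for immediate early genes, 0.20 for endothelial cells, 0.22 for smooth muscle cells and pericytes and 1.15 for tendon cells. Adjusted over the list alone, 3 clock genes were higher and 2 lower in females relative to males and 1 immediate early gene passed, while over all genes 0 passed with edgeR.

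Several of these calls depend on single libraries. Autophagy was not called without male LLC1 mouse 1-5 (median -0.09, adjusted p = 0.130) or male vehicle mouse 1-3 (0.0995), and extracellular matrix not without female LLC1 mouse 2-1 (0.30, 0.0624) or male vehicle mouse 1-3 (0.31, 0.0995). Immediate early genes were not called without female LLC1 mouse 2-4 (0.0922), female vehicle mouse 1-1 (-0.26, 0.0759), male LLC1 mouse 1-4 (0.0979) or male vehicle mouse 2-4 (0.0782). Oxidative phosphorylation was not called without female LLC1 mouse 2-3 (-0.06, 0.190), female vehicle mouse 2-1 (0.0901) or 2-2 (0.0633), male LLC1 mouse 1-4 (-0.05, 0.293) or male vehicle mouse 2-5 (0.0604). The circadian list was not called without any of female LLC1 mice 1-4, 2-3, 2-4 and 2-5 (0.0791, 0.0560, 0.0854 and 0.127), female vehicle mice 1-1, 1-3, 1-4 and 2-2 (0.103, 0.125, 0.0583 and 0.0733), male LLC1 mice 1-4 and 2-1 (0.155 and 0.0983) and male vehicle mice 1-1, 1-2, 2-4 and 2-5 (0.0591, 0.0602, 0.0782 and 0.0799). Smooth muscle was not called without any of female LLC1 mice 1-4, 2-1 and 2-3 (0.0600, 0.0988 and 0.0715), female vehicle mice 1-1 and 2-1 (0.0872 and 0.0747), male LLC1 mice 1-4, 2-4 and 2-5 (0.0545, 0.0863 and 0.0534) and male vehicle mice 1-3, 2-4 and 2-5 (0.133, 0.0596 and 0.0949). Tendon was not called without any of female LLC1 mice 1-4, 1-5, 2-1 and 2-3 (0.0795, 0.115, 0.287 and 0.0849), female vehicle mice 1-1, 1-4, 2-1, 2-2 and 2-3 (0.0555, 0.0525, 0.0901, 0.0733 and 0.245), male LLC1 mice 1-4, 1-5, 2-1 and 2-2 (0.114, 0.130, 0.0945 and 0.0719) and male vehicle mice 1-3 and 1-4 (0.217 and 0.121), with a median of 0.63 without female LLC1 mouse 2-1. The circadian and tendon calls also ended with upper-quartile scaling (0.0733 and 0.0727), and the circadian call without genes that share reads (0.0914). The glycolysis and glycogen list, not called in the interaction (median 0.10, camera adjusted p = 0.0555, adjusted p = 0.936 with an estimated correlation), passed with no filter (0.0309), without the 50 most abundant genes (0.15, 0.0381) and without any of 10 libraries (0.0122 to 0.0374).

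A mouse far from the other 5 of its group was found in 16 of 196 groups of values, where chance gives about 1 in 20 (5%), and 4 of the 16 were male vehicle mouse 1-3. That mouse had the highest Col3a1 (1042 CPM) and Isg15 (1.32 CPM) of its group, the lowest Myh4 (56959 CPM) and the lowest share of counts in the 10 most abundant genes (24.9%). Male vehicle mouse 1-4 had the highest total count (47.4 M) and the highest Foxo1 (35.3 CPM), male vehicle mouse 1-1 the highest Cdkn1a (30 CPM) and male vehicle mouse 2-4 the lowest Socs3 (1.84 CPM). Female vehicle mouse 2-1 had the highest Foxo6os (21.8 CPM) and Nrep (102 CPM), and female vehicle mouse 2-2 the highest Chil3 (1.03 CPM) and the lowest Mybph (437 CPM). Among LLC1 mice, female 2-4 had the highest Isg15 (29.0 CPM), female 2-1 the highest Ppargc1a (55.2 CPM), male 1-4 the highest Pnpla3 (8.42 CPM) and male 2-2 the lowest Cebpd (6.70 CPM).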

How the results depend on the processing

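Of the tests in this part, those without genes that share reads, and those of the correlation between the sexes other than with RLE scaling or a 1 CPM filter, were chosen only after the result was seen. No direction reversed for any named gene or list that passed. Over all settings that keep every library, 9001 values of named genes stayed on their side of the threshold, 180 passed newly and 459 no longer passed, and 1274, 20 and 17 values of lists did so. With 1 library left out these numbers were 16385, 135 and 184 for genes and 3442, 37 and 73 for lists. At 1.5-fold the share of simulated changes recovered was 14.7% in the interaction.

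Called genes moved by over 1.5 times in these settings. Limma-voom with sample quality weights called 4006 genes in females, 2 in the interaction and 2437 for the sex difference in vehicle mice, and DESeq2 called 44 in the interaction. The cause was not tested. A fit of only the LLC1 libraries called 966 for the sex difference in LLC1 mice, with fewer samples behind the dispersion. A threshold of 0.01 left 602 genes in females, 3765 in males, 4711 averaged over the sexes, 395 for the sex difference in vehicle and 989 in LLC1 mice, and a test against a 1.5-fold change, stricter by construction, left 163, 507, 453, 72 and 78. Without genes that share reads the counts were 1672, 5818, 0, 6620, 1025 and 2509 for females, males, interaction, average and the sex difference in vehicle and in LLC1 mice.

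With an estimated correlation camera called 1 list in females, 1 in males, 0 in the interaction and 1 for the sex difference in vehicle mice. With no expression filter 12 lists were called for that sex difference, and the correlation of fold changes between the sexes was 0.322, or 0.419 with DESeq2, both of which take in more genes of low count. Fry gave males an adjusted p of 0.00334 for proteasome subunits, 0.00131 for ribosomal proteins and 6.46e-04 for atrogenes, but 0.0561 for tendon cells. In females fry gave 0.037 for atrogenes and 0.00977 for nuclear-encoded oxidative phosphorylation, but 0.408 for proteasome subunits and 0.145 for extracellular matrix. Its lowest value in the interaction was 0.433, for cytosolic ribosomal proteins.

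Leaving out 1 library at a time gave 919 to 2283 genes in females, 4984 to 7154 in males, 0 to 7 in the interaction, 6675 to 7882 averaged over the sexes, 659 to 1476 for the sex difference in vehicle mice and 1606 to 3724 in LLC1 mice. The lists called were 16 to 20, 19 to 21, 9 to 14 in the interaction and 5 to 8 for the sex difference in vehicle mice, and the correlation between the sexes was 0.747 to 0.794.

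The full numbers in the titles do not pair the samples. Over 20 pairs of libraries with the same full number, the correlation of deviations from the group means had a median of 0.002 (-0.279 to 0.412), with 3 pairs above 0.1. None of the 3 female and 3 male pairs of LLC1 and vehicle mice correlated best with its own number (0 of 3 in each). With the full replicate number as a block the counts were 480 in females, 3607 in males, 3526 averaged over the sexes and 269 for the sex difference in vehicle mice, and the correlation between the sexes was 0.733. Pairs with the same first digit had a median of 0.029 (106 pairs, 30 above 0.1), against -0.015 for the others (110 pairs, 21 above 0.1). Between female LLC1 and vehicle mice the medians were 0.196 (-0.279 to 0.497, 10 of 18 above 0.1) and -0.157, so a shared structure by first digit is not excluded there. The first digits were also not spread evenly over the groups. The lower digit was more frequent among vehicle than among LLC1 mice, most so in males. A difference between the digits would therefore enter the LLC1 comparisons and the interaction in fits without that block. With the first digit as a block, edgeR called 6 genes in the interaction, among them Per2 (adjusted p = 0.00606), Arntl (0.0172), Cdkn1a (0.0329) and Hlf (0.0426). Among the calls that ended with the first digit as a block, and in brackets with the full number, were male Pdk4 at 0.0642 (0.319), female Col1a1 at 0.0523 (0.414), female fibro-adipogenic progenitors at 0.0719 (0.749) and male tendon cells at 0.0618 (0.0706). The tendon call of the interaction ended with the first digit (0.0953) and not with the full number. These list calls ended with the full number as a block and not with the first digit: female proteasome (0.907), autophagy (0.0890) and extracellular matrix (-0.08, 0.156), male interferon-stimulated genes (0.0521), circadian clock (0.114) and oxidative phosphorylation (0.418) in the interaction, and oxidative phosphorylation (0.148) and slow fibres (0.164) for the sex difference in vehicle mice. Some of them also ended in other settings, as given above. Macrophage markers were newly called in males with the first digit as a block (median 0.28, adjusted p = 0.0395), with Lyz2 (0.00459), Ctss (0.00554) and Ccr2 (0.0167), and with the full number in males (0.37, 0.00916) and females (0.41, 1.38e-04). Other lists newly called with the first digit were glycolysis in the interaction (0.0298) and, for the sex difference in vehicle mice, cholesterol and lipid synthesis (0.0442) and the circadian clock (0.0280), and with the full number fibro-adipogenic progenitors in the interaction (0.0290).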

Other observations

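No test in this part was chosen after the result was seen. Genes of the muscle fibre itself moved in both sexes. The mechanical stress gene Ankrd2 rose by 1.53 ± 0.37 in females and 1.66 ± 0.37 in males (SE, n = 6 per group, edgeR adjusted p = 0.0108 and 0.00175), while Myl1, a fast myosin light chain gene, fell by 0.72 ± 0.14 and 0.66 ± 0.14 and the calcium store gene Casq1 was at -0.86 ± 0.23 and -1.05 ± 0.23. The female call of Casq1 was lost without female LLC1 mouse 1-4 (adjusted p = 0.0513) or 2-3 (0.0637). Of 16 fast-fibre genes, 4 fell and 1 rose in females (7 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 0.0170, adjusted p = 0.723 with an estimated correlation) and 6 fell and 1 rose in males (9 and 1, median -0.30, camera adjusted p = 0.0152, adjusted p = 0.597 with an estimated correlation). The female list was not called without female LLC1 mouse 1-4 (-0.09, 0.0513), 1-5 (-0.09, 0.0536) or 2-1 (0.0698). Of 14 slow-fibre genes, 1 rose in females and 2 in males, adjusted over the list alone too (medians 0.20 and 0.20, camera adjusted p = 0.199 and 0.509), and the female list passed without female vehicle mouse 2-2 (0.50, 0.0170). Of 25 glycolysis and glycogen genes, 12 fell and 2 rose in males (14 and 2 adjusted over the list alone, median -0.30, camera adjusted p = 0.00701, adjusted p = 0.593 with an estimated correlation), with Pgam2 at -0.98 ± 0.20 and the glucose transporter gene Slc2a1 at 0.62 ± 0.11, a call of the list lost when scaled without the 50 most abundant genes (0.0581). In females 5 fell and 3 rose (8 and 4, median -0.14, camera adjusted p = 0.106, passing without female LLC1 mouse 2-5 at 0.0117 or male LLC1 mouse 1-5 at 0.0271). Of 21 denervation and neuromuscular junction genes, 2 rose and 2 fell in females and 5 rose and 8 fell in males, adjusted over the list alone too (medians -0.11 and -0.06, camera adjusted p = 0.798 and 0.755, with a male mean of 0.07). The receptor kinase gene Musk (0.98 ± 0.20), Runx1 (1.26 ± 0.27) and Ampd3 (1.54 ± 0.34) rose in males and the agrin receptor gene Lrp4 fell (-0.58 ± 0.13). Of 21 genes of myogenic regulation, 2 rose and 2 fell in females (3 and 2 adjusted over the list alone, median 0.01, mean -0.01, camera adjusted p = 0.883) and 9 rose and 6 fell in males (10 and 6, median 0.25, camera adjusted p = 0.369), with Myf6 at 0.56 ± 0.12 and 0.89 ± 0.12 and the activin subunit gene Inhbb at 2.22 ± 0.39 in males.

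Stress and lipid genes also moved. Of 22 genes of cholesterol and lipid synthesis, 11 fell and 1 rose in males, adjusted over the list alone too (median -0.39, camera adjusted p = 9.92e-04, adjusted p = 0.562 with an estimated correlation), with Dhcr7 at -1.11 ± 0.21, and 3 fell in females (15 adjusted over the list alone, median -0.39, camera adjusted p = 1.62e-05, adjusted p = 0.409 with an estimated correlation). Those 3, Msmo1, Insig1 and Fdps, were not called without female LLC1 mouse 2-3 (adjusted p = 0.0540, 0.0507 and 0.0649), and Fdps not without female LLC1 mouse 1-4 (0.0523) or female vehicle mouse 2-1 (0.0676). Of 16 heat shock genes, 7 rose in males (8 adjusted over the list alone, median 0.44, camera adjusted p = 0.0152, adjusted p = 0.593 with an estimated correlation) and 1 in females, the chaperone gene Hsp90ab1 at 0.53 ± 0.12 (6 adjusted over the list alone, median 0.24, camera adjusted p = 0.0115, adjusted p = 0.616 with an estimated correlation, not called without female LLC1 mouse 2-1 at 0.13 and 0.0643). Of 20 genes of the unfolded protein response, 1 rose in females, Chac1 (2.35 ± 0.41), adjusted over the list alone too (median 0.16, camera adjusted p = 0.0170, adjusted p = 0.471 with an estimated correlation, not called without female LLC1 mouse 2-1 at 0.0825). In males 4 rose and 2 fell (4 and 1, median 0.09, camera adjusted p = 0.151), with Atf4 at 0.80 ± 0.13. Of 18 immediate early genes, 6 rose in males, adjusted over the list alone too (median 0.33, camera adjusted p = 0.0329, adjusted p = 0.597 with an estimated correlation), and the list was not called without male LLC1 mouse 1-4 (0.14, 0.135) or male vehicle mouse 1-4 (0.26, 0.0509) or 2-4 (0.17, 0.144). In females 2 rose, Ier3 (1.23 ± 0.17) and Maff (0.85 ± 0.19), adjusted over the list alone too, with a median of -0.13 where camera put the list higher (adjusted p = 0.798). Of 32 interferon-stimulated genes, 9 fell in males, adjusted over the list alone too (median -0.20, camera adjusted p = 0.00166, adjusted p = 0.593 with an estimated correlation), led by the chemokine gene Cxcl9 (-2.55 ± 0.33). In females Cxcl9 fell (-1.99 ± 0.30) and 2 rose, adjusted over the list alone too (median -0.16, camera adjusted p = 0.326): Isg15 at 2.28 ± 0.56 and Rsad2 at 2.11 ± 0.54, which were 0.95 and 0.87 (not called, 0.0724) without female LLC1 mouse 2-4. With limma-voom both calls were lost (0.0655 and 0.0925), and in a fit of the female libraries alone too (0.0575 and 0.0580). Of 18 clock genes, 3 rose and 1 fell in females (5 and 2 adjusted over the list alone, median 0.16, camera adjusted p = 0.0668) and 5 rose and 5 fell in males (5 and 6, median -0.14, camera adjusted p = 0.872). Per2 rose in females (0.94 ± 0.22), and in males Arntl rose (1.18 ± 0.22) and Hlf fell (-1.03 ± 0.17). The female clock list passed without female LLC1 mouse 2-1 (0.0348), female vehicle mouse 2-1 (0.0455) or 2-3 (0.0328) or male LLC1 mouse 1-4 (0.0469), with no filter (0.0359) and in a fit of the female libraries alone (0.0366).

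Markers of other cells were mixed. Of 11 endothelial markers, 5 rose in females, adjusted over the list alone too (median 0.21, camera adjusted p = 3.35e-04, adjusted p = 0.409 with an estimated correlation), and 4 rose and 3 fell in males, adjusted over the list alone too (median 0.05, camera adjusted p = 0.755). Vwf rose by 0.84 ± 0.17 and 0.64 ± 0.17 and Pecam1 by 0.51 ± 0.12 and 0.54 ± 0.12, while Kdr, a receptor for VEGF, fell in males (-0.62 ± 0.14). Of 8 smooth muscle and pericyte markers, 4 fell in males (5 adjusted over the list alone, median -0.34, camera adjusted p = 0.0217, adjusted p = 0.593 with an estimated correlation, not called without male vehicle mouse 1-3 at 0.0609) and 0 passed in females with edgeR, adjusted over the list alone too (median -0.11, camera adjusted p = 0.406). Of 7 B cell markers 4 rose and 1 fell in males (5 and 1 adjusted over the list alone, median 1.79, camera adjusted p = 0.428). Without male LLC1 mouse 1-4 that median was 0.58, Cd79b was at 0.69 in place of 1.96 and Ms4a1 at 0.67 in place of 2.45 (adjusted p = 0.155 and 0.448). Both calls were lost with limma-voom (0.0730 and 0.183), and that of Ms4a1 without male vehicle mouse 1-2 (0.0579) or 2-4 (0.0551) and with no filter (0.0663). In females 0 B cell markers passed with edgeR, adjusted over the list alone too, and the median was 0.76 where camera put the list lower (adjusted p = 0.990), or -0.35 without female LLC1 mouse 2-4. Of 4 T and NK cell markers, Thy1 fell in both sexes (-1.37 ± 0.32 and -1.46 ± 0.33) and Cd4 rose in males (1.89 ± 0.66, adjusted p = 0.0290), with 2 rises in males adjusted over the list alone. Thy1 was the 1 call in females, adjusted over the list alone too. Cd4 was at 0.38 (0.490) without male LLC1 mouse 1-4 and was not called without male vehicle mouse 1-4, 2-4 or 2-5 (0.0552, 0.0558 and 0.0528), with limma-voom (0.226) or with no filter (0.0573). The medians of this list were 0.05 in females (mean -0.19) and 0.93 in males, where camera put it lower (adjusted p = 0.607 and 0.872), and -0.42 in males without male LLC1 mouse 1-4.

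The other lists were not called by camera in either sex. Of 23 genes of mitochondrial biogenesis and dynamics, 1 rose and 1 fell in females (1 and 2 adjusted over the list alone, median -0.08, mean 0.01, adjusted p = 0.632) and 5 rose and 7 fell in males (5 and 8, median -0.06, adjusted p = 0.427). The uncoupling protein gene Ucp2 rose in females (0.99 ± 0.21), the fission gene Dnm1l fell in both sexes (-0.33 ± 0.07 and -0.32 ± 0.07) and the coactivator gene Ppargc1b fell in males (-1.14 ± 0.20). Of 26 genes of fatty acid oxidation, 5 rose and 3 fell in males (4 and 2 adjusted over the list alone, median 0.01, adjusted p = 0.831), among them Ppard (0.51 ± 0.09). In females 1 fell, Hadh, and 0 adjusted over the list alone (median -0.05, mean 0.06, adjusted p = 0.798). Hadh (-0.29 ± 0.08) was not called without any of female LLC1 mice 1-4, 2-1 and 2-3 and female vehicle mice 1-3, 2-1, 2-2 and 2-3 (adjusted p = 0.0563 to 0.111). Of 15 androgen-responsive genes, 2 rose and 1 fell with LLC1 in females and 5 rose and 6 fell in males, adjusted over the list alone too (medians 0.03 and -0.11, female mean -0.07, adjusted p = 0.798 and 0.549). Of 16 cell cycle genes 0 passed in females with edgeR, and 2 rose and 1 fell in males, adjusted over the list alone too (medians 0.01 and 0.24, adjusted p = 0.639 and 0.310), with Pcna at 0.36 ± 0.09. Of 11 adipocyte markers 0 passed in females with edgeR and 1 rose in males, Plin4 (0.86 ± 0.21), adjusted over the list alone too (medians -0.06 and -0.02, means 0.01 and 0.04, camera higher in both, adjusted p = 0.883 and 0.831). Of 9 Schwann cell and 3 epithelial markers 0 passed with LLC1 in either sex with edgeR, adjusted over the list alone too (Schwann medians 0.03 and -0.03, adjusted p = 0.883 and 0.820). The epithelial medians were 0.12 in females, where mean and test lay lower, and 0.67 in males (adjusted p = 0.872 in both), or -0.61 without female LLC1 mouse 2-5 and 0.03 without male LLC1 mouse 1-5.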
